A study of Mus musculus with 2 samples.

How the data were processed

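Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K36me3, the trimethylation of lysine 36 of histone H3, in limb tissue of mouse embryos of strain B6NCrl at embryonic day 15.5. Per the labels, 2 biological replicates were made, from limbs of 78 embryos of both sexes for replicate 1 and of 62 for replicate 2. Each replicate joined 2 technical replicates, and the library fragments were selected between 300 and 500 bp. The labels give a single group, so the comparisons are those between the replicates, between classes of sequence, between gene groups and between chromosomes within these libraries.

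The authors deposited 4 lists of narrow peaks in mm10 coordinates. Per the text deposited with the files, each replicate's list was called from its filtered alignments against the same 2 control alignments, the pooled list from the alignments of both replicates, and the list called replicated from the other 3. The aligner, the peak caller and their settings are not given in the sources used here. Each peak carries a fold enrichment, a linear ratio deposited by the authors, and the −log10 of a p-value and of a q-value, also as deposited. The smallest −log10 p-value in the deposited lists was 2.00, so the lists hold peaks down to a p of about 0.01. At so lenient a threshold part of the peaks are weak, and thresholds of 2 and 5 on −log10 q were therefore tried as alternatives. The fold and p-values are the authors' own and were used as deposited, to describe, rank and filter peaks and to compare peaks of different genes or chromosomes within a list.

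Peak lists hold no read counts, so the sequencing depth of either library is unknown and no counting interval can be given for a coverage value. A base outside a peak did not pass the caller's threshold in that library, which is not evidence that the mark was absent there. Because a deeper or more enriched library yields wider and more numerous peaks, differences in covered length between the replicates cannot be read as differences in the mark.

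Peaks of each replicate on the 19 autosomes and on X and Y were merged, and the measure was the percent of bases covered by peaks, given as the mean ± SD of the 2 replicates. Gene models were those of GENCODE M21 on GRCm38, the assembly named mm10 in the lists, and no peak ran past a chromosome end of that assembly. Protein-coding genes of at least 2 kb were tested, 20350 in all. A gene was called marked when at least 10% of its body was covered in both replicates. Of the tested genes, 48.0% overlapped another annotated gene, and there the lists cannot assign a peak to one of the pair. Promoters were the 1 kb on either side of a gene start. Internal exons were compared with introns in genes of at least 5 kb with a peak in both replicates, and also with 150-bp intron windows of the same gene, drawn at random, matched on GC content within 2 percentage points, or matched on the segment of the gene body. The profile along the gene used 10 equal segments of the body, with the last 3 set against the first 3.

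Replicate agreement was the shared length over the joint length of covered bases (Jaccard index), beside 100 circular shifts of replicate 2 along each chromosome. The exon and 3′ comparisons used exact two-sided sign-flip permutation tests over the 19 autosomes, whose smallest possible p is 3.8e-06. Chromosomes and genes are parts of the same libraries and not biological replicates, so these p-values describe the libraries at hand. Each of 22 gene lists was set against 100000 random lists of coding genes matched on gene length in 20 bins. The median of a list was taken over the means of the replicates per gene and is given beside the SD of the medians of the single replicates, so it need not lie between them. The test was a two-sided permutation test on that median, with Benjamini-Hochberg adjustment over the lists. The smallest raw p it can give is 2e-05. One X chromosome against 19 autosomes allows no test at 0.05, and a single library on each side allows none of a gene between replicates.

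The gene lists, tests and alternatives were fixed before the data were examined, as was the rule for the genes named, while the tests on the X chromosome, the intron windows matched on the segment and a few other alternatives were added afterwards. That rule took the 2 most and the 1 least covered member of each list, all members of the H3K36 methylation list, members at 0, and the 10 most covered coding genes of at least 10 kb. It also took the 5 such genes that differed most between replicates in each direction, the 10 replicated peaks of highest fold, the 5 longest domains and the 5 most covered non-coding genes of at least 5 kb clear of coding genes. Genes outside the rule are marked as chosen after their values were seen. Alternatives were a stricter q, only the 88141 peaks of smallest p in each replicate (50% of the number in the shorter list), joining of peaks over gaps of up to 1 kb, the replicated list, each replicate alone, genes that overlap no other, other limits for a marked gene, and the percent of list members marked in place of the median.

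Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The statistics were tested on peaks simulated in 10575 coding genes that overlap no other. The simulated and measured percent covered had a Spearman's rho of 0.991 across those genes. In 200 genes raised by a median of 20 percentage points the measured median gain was 19.3. An end-to-start ratio set at 2.08 was measured as 2.10, and an exon-to-intron ratio set at 2 as 2.06. The exon simulation used the same rates in all genes and at all positions. It therefore tests the arithmetic and not how differences between genes or position shape the measured ratio. None of 20 unchanged lists reached a p under 0.05.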

Results

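H3K36me3 is laid down over the bodies of transcribed genes by enzymes that travel with elongating RNA polymerase II, and it was profiled here in whole mouse limb at embryonic day 15.5, a tissue that holds cartilage, bone, muscle, connective tissue, skin, vessels and nerve. Replicate 1, from limbs of 78 embryos, had 176283 peaks, which covered 90.6 Mb or 3.42% of the sequenced genome. Replicate 2, from 62 embryos, had 198874 peaks, which covered 119.1 Mb or 4.50%. The median peak was 336 bp wide in replicate 1 and 354 bp in replicate 2, with a median fold enrichment by the authors of 2.93 and 3.13. The authors' replicated list held 124767 peaks over 115.7 Mb, each of them identical in position to a peak of the pooled list. Peaks of both replicates touched 83.4% of the replicated peaks. The number of reads behind each list is unknown.

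The biological replicates shared far more covered sequence than shifted peaks did. They shared 73.3 Mb, which was 53.8% of the bases covered in either, against 2.22% on average and at most 2.52% when replicate 2 was shifted along its chromosomes. Replicate 2 covered more sequence by a factor of 1.31, and the overlap was therefore uneven: 82.9% of replicate 1 peaks met a replicate 2 peak and 62.9% of replicate 2 peaks met a replicate 1 peak. With shifted peaks these shares were at most 8.30% and 6.80%. The shifts move peaks off their genes, so they do not test agreement beyond a common location in genes. Across the 20350 tested genes the percent of the gene body covered had a Spearman's rho of 0.971 and a Pearson's r of 0.982 between replicates. Of these genes 41.5% had no covered base in either replicate, which enters both values, and genes are not independent replicates.

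Peaks lay almost wholly inside protein-coding genes. Gene bodies of coding genes held 94.5% ± 0.150 (SD, n = 2) of the covered bases, although they make up 39.2% of the sequenced genome. Coding exons held 23.7% ± 1.24 of covered bases against 3.26% of the genome, an excess of 7.28-fold, and introns held 70.5% ± 1.12 against 35.1%, an excess of 2.01-fold. Promoters held 0.408% ± 0.0225 of covered bases against 1.56% of the genome. Sequence outside all genes held 4.53% ± 0.0915 against 53.4%. Each of these gaps to the genome share was many times the SD between replicates.

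Within genes, exons were covered more than introns. Over 9707 genes, 52.9% ± 6.03 (SD, n = 2) of internal-exon bases and 13.7% ± 2.84 of intron bases lay in peaks. The ratio was 4.15 in replicate 1 and 3.63 in replicate 2, and it was above 1 on 19 of 19 autosomes (exact two-sided sign-flip permutation test, p = 3.8e-06, the smallest it can give). The excess was smaller within single genes. Against random intron windows of the same gene the ratio was 2.03 ± 0.112, against windows matched on GC content 1.75 ± 0.0440, and against windows in the same of 10 equal segments of the gene 1.40 ± 0.0558. With both GC content and segment matched it was 1.23 ± 0.0162. Each of these ratios kept the same p of 3.8e-06 in the permutation test over the autosomes.

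Coverage rose from the start of genes towards their end. In 17798 coding genes of at least 5 kb, 2.35% ± 0.575 (SD, n = 2) of the first of 10 equal segments was covered, 18.2% ± 3.01 of the fifth, 25.4% ± 3.50 of the ninth and 25.1% ± 3.56 of the last. The last 3 segments were covered more than the first 3 by a factor of 3.47 in replicate 1 and 3.15 in replicate 2, again on 19 of 19 autosomes (exact two-sided sign-flip permutation test, p = 3.8e-06).

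**Figure D1:**
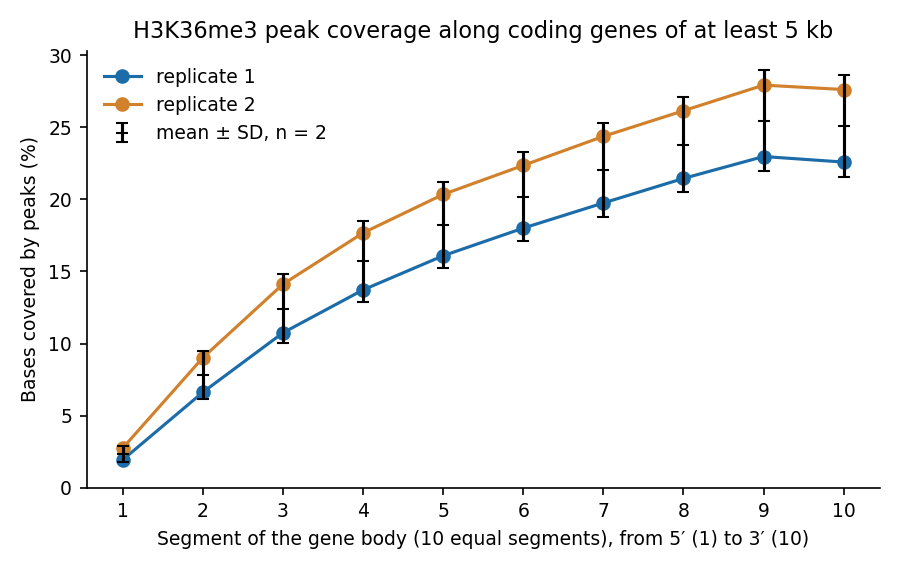
Percent of bases covered by H3K36me3 peaks (y axis) in each of 10 equal segments of the gene body from 5′ to 3′ (x axis), for coding genes of at least 5 kb. Lines are the 2 replicates and black bars the mean ± SD, n = 2. Coverage climbs from 2.35% in the first segment to 25.4% in the ninth in the mean, with replicate 2 above replicate 1 in every segment.

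Of the 20350 coding genes tested, 7697 (37.8%) were marked in both replicates, and 8448 (41.5%) had no covered base in either. Among genes of at least 10 kb the most fully covered was Trrap, which encodes a scaffold of histone acetyltransferase complexes, on chromosome 5 (144767732 to 144859778), covered over 89.7% ± 3.11 (SD, n = 2) of its body. Fasn, the fatty acid synthase, reached 89.1% ± 0.0529, and Exosc10, a catalytic part of the RNA exosome, 88.7% ± 2.13. Ints1, a subunit of the Integrator complex, Copg1, a subunit of the COPI coat, Mybbp1a, Ddb1, a part of a DNA damage recognition complex, Rnf40, Ube3b and Gm49388 followed, all between 86.6% and 88.3%. Of these 10 genes all but Fasn overlapped another annotated gene.

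Genes of general cell functions were covered above length-matched lists. All 28 splicing and RNA processing genes were marked, with a median of 49.9% ± 8.74 of the body covered (SD of the replicate medians, n = 2) against 5.17% in the matched lists. Sf3b3 and Sf3a1, both of the U2 small nuclear ribonucleoprotein, reached 86.3% ± 6.62 and 84.6% ± 1.23, and Cpsf6, a cleavage factor subunit, was lowest at 22.2% ± 8.09. All 28 cell cycle genes were marked as well, with a median of 53.9% ± 11.3 against 6.63%. The replicative helicase subunits Mcm2 and Mcm5 reached 77.4% ± 9.65 and 77.4% ± 5.72, and the mitotic cyclin gene Ccnb1 was lowest at 21.1% ± 11.4. With peaks of a −log10 q of at least 5, 26 splicing and 21 cell cycle genes stayed marked, and Ccnb1, at 8.92%, did not. Ribosomal protein genes were marked in 61 of 68 cases with a median of 48.6% ± 5.59, led by Rps3 at 74.3% ± 0.0968, and the median was 73.1% without the first 1 kb of each gene. Housekeeping genes were marked in 28 of 30 cases with a median of 46.1% ± 6.81, led by Gpi1, a glycolytic enzyme, at 84.5% ± 4.71, while the tubulin gene Tuba1b had 1.00% ± 1.15. For the splicing, cell cycle and ribosomal lists the adjusted p was 8.8e-05 in the two-sided permutation test, the smallest it can reach for them, and for the housekeeping list 0.00022.

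Like the lists of general cell functions above, the H3K36 methylation list was covered. It holds genes that write, erase and read this methylation, with the elongation factor genes Supt6 and Iws1. Polr2a, of RNA polymerase II, is in it and in the housekeeping list. Of its 24 genes 22 were marked, with a median of 43.3% ± 8.81 against 5.74% in matched lists (permutation test, adjusted p = 8.8e-05). Kdm4a, a demethylase, was highest at 86.4% ± 5.36, and Supt6, an elongation factor that binds RNA polymerase II, had 74.1% ± 4.71. Setd2, the main H3K36 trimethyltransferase, had 43.6% ± 8.82, and the dimethyltransferase genes Nsd1, Nsd2 and Nsd3 had 54.4% ± 12.3, 42.6% ± 7.20 and 38.1% ± 7.999. Of the DNA methyltransferases whose PWWP domain binds methylated H3K36, Dnmt3a had 43.0% ± 6.80 and Dnmt3b 14.6% ± 4.54. With a −log10 q of at least 5, 18 of the 24 genes were marked. Dnmt3a then had 25.4%, Nsd3 23.9%, Kdm4c 4.40%, Kdm2b 2.95% and Dnmt3b 1.68%. The 2 members not marked with the full lists were Kdm2b and Kdm4c, at 10.3% ± 0.552 and 13.3% ± 6.37, each under 10% in replicate 1. Most members overlapped another gene, and with the 5 that did not the median was 46.0% and the call was lost (permutation test, adjusted p = 0.106).

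Among the lists of limb cell types, that of tendon and connective tissue was covered above length-matched lists. The median of the 24 tendon and connective tissue genes was 29.4% ± 7.54 (SD of the replicate medians, n = 2) against 3.78% in matched lists (permutation test, adjusted p = 0.0071). The size of this median depends on the peaks taken, with 15.9% at a −log10 q of at least 5 and 50.6% with peaks joined over 1 kb, and the list passed in both. Of these genes 14 were marked. Col6a1, a chain of collagen VI, had 83.4% ± 0.110 of its body covered and Fn1, fibronectin, 71.2% ± 12.1, while Scx, a tendon transcription factor, and Tnmd were at 0 in both replicates. By the share of genes marked, 58.3% against 37.5% in matched lists, the list did not pass (permutation test, adjusted p = 0.073). In the bone list 3 of 16 genes were marked. The pair of chains of collagen I, Col1a1 on chromosome 11 (94936224 to 94953042) and Col1a2, had 69.6% ± 6.09 and 56.7% ± 11.9, and the third, Postn, had 28.7% ± 8.80, was named after its value was seen and was not marked at a −log10 q of at least 5. The osteoblast genes Sp7, Spp1, Ibsp and Dmp1 were at 0. In the cartilage list 7 of 27 genes were marked, with Col27a1 at 61.5% ± 9.21 and Col2a1, the main cartilage collagen, at 44.6% ± 4.53, while Matn1, Matn3 and Ucma were at 0. Of the 7 genes 4 stayed marked at a −log10 q of at least 5, with Col27a1 at 36.8% and Col2a1 at 29.2%. Neither the bone nor the cartilage list passed against matched lists (permutation test, adjusted p = 0.68 for both medians). The bone median was 0, as was the lower bound of its matched lists, so that test could not show lower coverage. The share marked was 18.75% against 37.5% for bone and 25.9% against 37.0% for cartilage. Neither list passed on it (permutation test, adjusted p = 0.246 and 0.274).

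Limb patterning genes were seldom marked. Of 36 such genes 4 were, or 11.1% against 36.1% in length-matched lists (permutation test on the share marked, adjusted p = 0.0024). These were Ptch1, the Hedgehog receptor, at 44.1% ± 6.18, Tbx4, a hindlimb T-box factor, at 30.4% ± 9.22, and Wnt5a and Bmp2, chosen after their values were seen, at 17.6% ± 3.44 and 15.1% ± 0.936. Only Ptch1 stayed marked at a −log10 q of at least 5, with Tbx4 at 9.01%, Wnt5a at 3.00% and Bmp2 at 4.06%. Shh, Fgf8, Pitx1, Msx1, Hand2, Twist1 and Dlx5 were among the 13 at 0 in both replicates. None of the 38 Hox genes was marked, against 31.6% in matched lists (permutation test on the share marked, adjusted p = 4.9e-05). The most covered Hox genes, Hoxd10 and Hoxa5, had 11.4% ± 7.53 and 7.06% ± 9.98, and 33 of the 38 were at 0, Hoxa13, Hoxd12 and Hoxd13 among them. The values of the former pair were unstable: in the authors' replicated list Hoxd10 was at 0 and Hoxa5 at 23.2%, past the 10% limit.

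**Figure D2:**
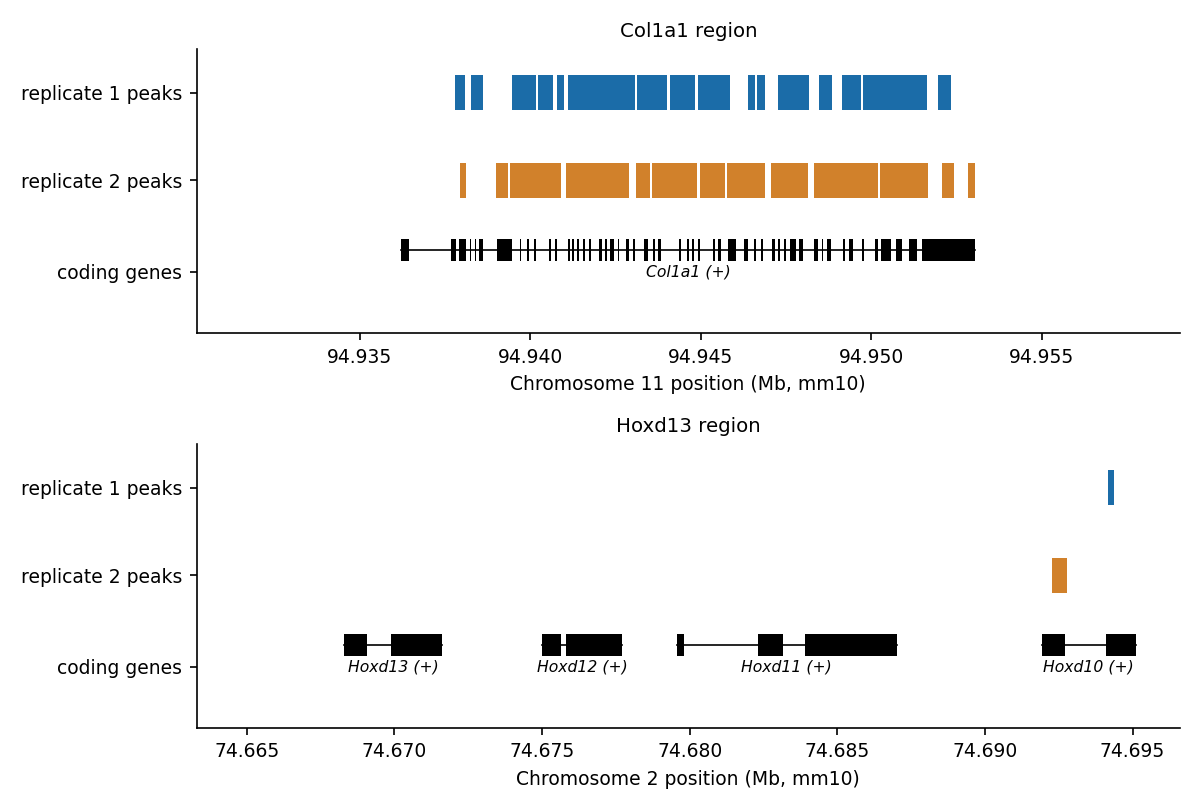
Peaks of the 2 replicates (coloured blocks) and coding genes (black, exons as boxes, strand in parentheses) along the chromosome position in Mb of mm10, for Col1a1 above and the Hoxd13 to Hoxd10 interval below. Peaks cover 65.3% and 73.9% of Col1a1 in replicates 1 and 2, and neither replicate has a peak in Hoxd13, Hoxd12 or Hoxd11.

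Most genes of muscle, skin, vessels, blood and nerve had little or no coverage. In the skeletal muscle list 1 of 31 genes was marked, Atp2a1, the calcium pump of fast fibres, at 16.7% ± 2.55. Acta1, Myh3, Myod1 and Myog were at 0. In the epidermis list 1 of 21 was marked, Jup, plakoglobin, at 40.9% ± 5.78, with Krt5 and Krt14 at 0, and in the endothelium list 1 of 14, Eng, endoglin, at 16.5% ± 2.20, with Cdh5 and Kdr at 0. Neither Atp2a1 nor Eng was marked at a −log10 q of at least 5, with 9.08% and 4.67%, and Jup fell to 25.7%, while Eng had 32.0% with peaks joined over 1 kb. None of 12 erythroid genes and none of 22 neuronal genes was marked. The same held for 19 liver genes, 10 heart genes and 997 olfactory receptor genes, lists of tissues outside the limb. Whether limb tissue holds the nuclei of neurons was not examined, so the neuronal list may not stand for limb nerve. In all 8 of these lists the share of marked genes was below that of matched lists, with adjusted p between 4.9e-05 for muscle and olfactory receptors and 0.027 for endothelium and heart (permutation test). These calls and those of the patterning and Hox lists rest on the share marked, an alternative fixed in advance. On the median none of the 10 lists passed (adjusted p from 0.101 to 1), since 9 medians were under 0.1% and the medians of matched lists often reached 0 as well. In the macrophage and leukocyte list 2 of 15 genes were marked, Fcer1g at 20.1% ± 1.92, which fell to 9.36% at a −log10 q of at least 5 and to 0.356% without the first 1 kb of the gene, and Cx3cr1 at 18.1% ± 1.51, and in the Schwann cell list 1 of 12, Pmp22, at 58.5% ± 6.31. Neither list passed on the share marked (permutation test, adjusted p = 0.168 and 0.0515).

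**Figure D3:**
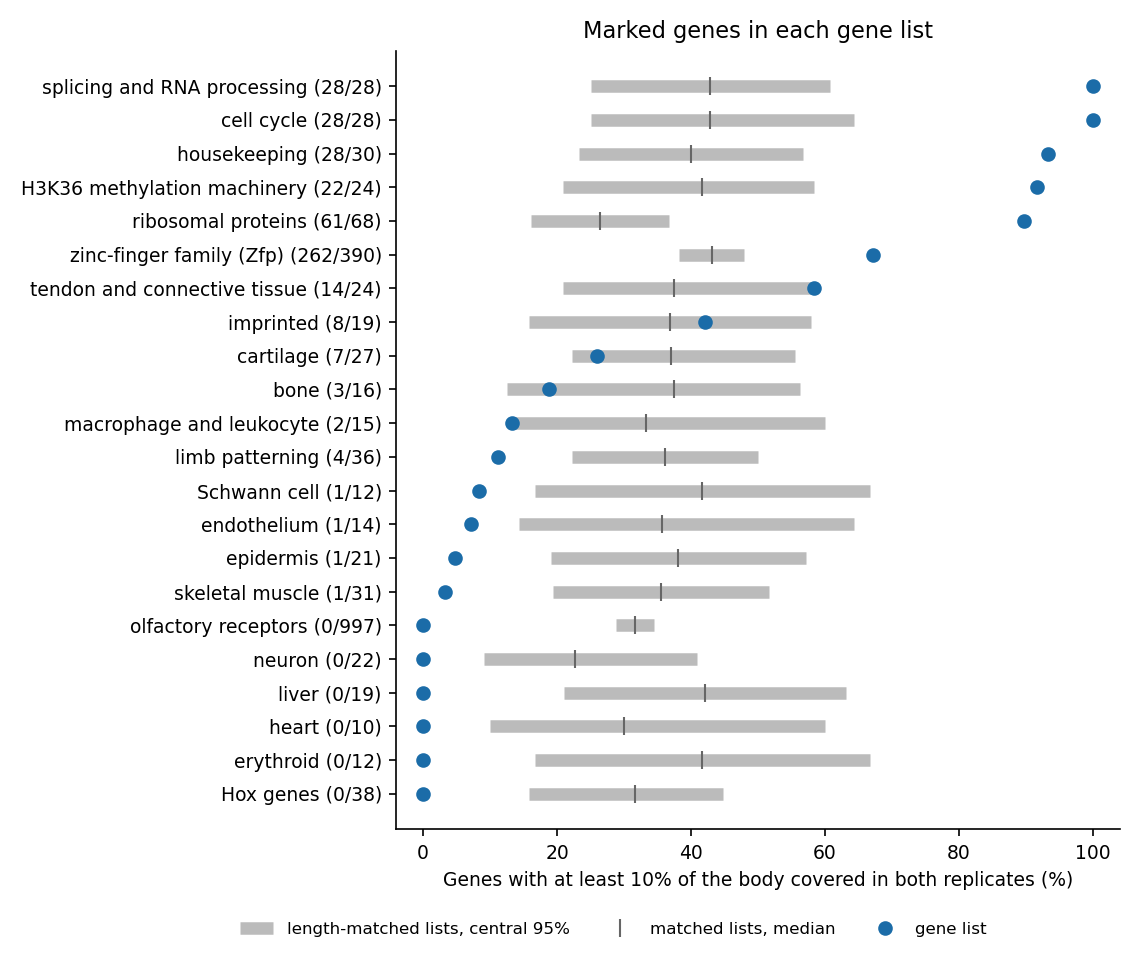
Percent of genes in each list with at least 10% of the body covered in both replicates (x axis), with marked and measured genes in parentheses. Blue points are the lists, grey bars the central 95% of length-matched random lists and ticks their median. Splicing and cell cycle lists stand at 100%, and the Hox list at 0.

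The imprinted list did not pass against matched lists, with 8 of 19 genes marked (permutation test on the median, adjusted p = 0.68). Its median was 8.27% over the means of the replicates per gene, below the 8.68% and 9.12% of replicates 1 and 2 alone. It was 1.82% at a −log10 q of at least 5 and 14.2% with peaks joined over 1 kb, and did not pass in either. Igf2r, the mannose-6-phosphate receptor, had 50.7% ± 6.63 and Peg3, a zinc-finger gene, 48.0% ± 8.22, while Ndn was at 0. Under the stricter q Igf2r had 33.7% and Peg3 31.8%. Genes named Zfp, a family of DNA-binding zinc-finger proteins, were covered above matched lists. Of 390 such genes 262 were marked, with a median of 25.6% ± 4.58 against 5.03% (permutation test, adjusted p = 8.8e-05), led by Zfp869 at 87.4% ± 4.30 and Zfp110 at 86.1% ± 2.18.

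The peaks of highest fold also lay in Zfp genes. Of the 10 strongest peaks of the replicated list 8 overlapped one, as did 50 of the 100 strongest and 129 of the 1000 strongest. Among all replicated peaks the share was 1.98%. The strongest, with an authors' fold of 15.0, covered chromosome 7 from 5027394 to 5034207 at Zfp865, Ccdc106, Gm44973 and 4632433K11Rik. Coding sequence made up 46.7% of it, untranslated exon 21.8% and intron 23.4%. It was followed by peaks at Zfp146 on chromosome 7 (30160627 to 30164416, fold 13.5) and Zfp354c on chromosome 11 (50810007 to 50818676, fold 12.4). The other 2 peaks were in genes without a Zfp name. They were at Plec, which encodes the cytoskeletal linker plectin, on chromosome 15 (76169306 to 76184818, fold 12.1), and at 2610008E11Rik on chromosome 10 (fold 10.8). Zfp genes were taken by name alone, so zinc-finger genes of other names are not in these counts. When replicated peaks were joined over gaps of up to 1 kb they formed 40638 domains, 3767 of them of at least 10 kb. The longest ran over Ubr4, a ubiquitin ligase gene on chromosome 4 (139389135 to 139492774, 103.6 kb), followed by Wdfy3 (102.6 kb), Chd2, a chromatin remodeller gene (95.6 kb), Col5a1, a collagen V chain (94.0 kb), and Trrap (91.5 kb).

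Coding genes of the X chromosome were covered far less than those of any autosome. On X, 1.04% of coding gene-body bases lay in replicate 1 peaks and 1.84% in replicate 2 peaks, against 8.61% and 11.3% over all autosomes, a gap of 8.30-fold and 6.14-fold. The least covered autosome, 14, had 7.10% ± 1.53 (SD, n = 2) and the most covered, 11, had 14.4% ± 2.51, so X lay below all 19 autosomes in both replicates, a ranking that allows no test. Of 791 X-linked coding genes 77 (9.73%) were marked, against 7620 of 19408 autosomal ones (39.3%). The 6 X-linked members of the lists of general cell functions, chosen after their values were seen, were Pgk1, which was marked at 23.7% ± 3.58 (5.81% and not marked at a −log10 q of at least 5), Rps4x at 16.1% ± 11.4 (4.01%), Rpl39 at 8.17% ± 11.6 (0), Hprt at 4.37% ± 2.88 (0.792%), and Rpl10 and Rpl36a, both at 0. At a −log10 q of at least 5 the gap widened to 23.3-fold and 14.8-fold, and with only the 88141 peaks of smallest p kept in each replicate, which is also a stricter list, to 16.7-fold and 13.4-fold.

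**Figure D4:**
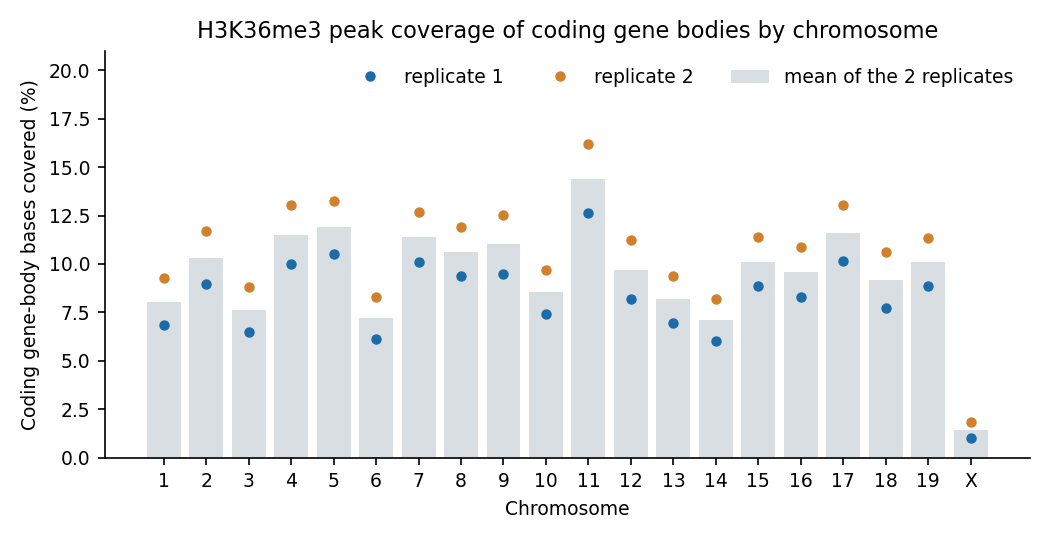
Percent of coding gene-body bases covered by H3K36me3 peaks (y axis) on each autosome and on X (x axis). Bars are the mean of the 2 replicates and points the replicates. Chromosome 11 is highest at 14.4% and X lowest at 1.44% in the mean.

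Most marked genes were covered over a larger part in replicate 2. Of the marked genes 93.2% were covered more in replicate 2, and the median over marked genes was 34.5% in replicate 1 and 44.0% in replicate 2. Marked in replicate 2 alone were 883 genes, and in replicate 1 alone 58. With only the 88141 peaks of smallest p in each replicate the counts were 882 and 126, so the number for replicate 1 depends on the lists. The largest excess in replicate 2 among genes of at least 10 kb was in AC115631.1, at 32.1% and 61.5%, followed by Kctd17, at 14.2% and 42.3%, Zc3hav1l, Accs and Dsn1. The largest excess in replicate 1 was in Cmtm6, at 30.4% and 17.7%, followed by Aen, at 38.5% and 30.6%, Bok, Tubb6 and Plekhf1. With peaks of a −log10 q of at least 5 the former 5 genes kept their excess in replicate 2, but of the latter only Aen kept one in replicate 1, at 25.2% and 10.8%. Cmtm6 then had 5.92% and 10.8%, Tubb6 12.3% and 13.5%, Plekhf1 0 and 1.85%, and Bok was at 0 in both. With 1 library on each side these differences were not tested.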

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

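A few peaks lay on scaffolds, which were left out of the coverage values, and on the Y chromosome. On unplaced or unlocalized scaffolds replicate 1 had 23 peaks and replicate 2 had 22, with an authors' fold of up to 7.20 and 8.70. On the Y chromosome replicate 1 had 5 peaks and replicate 2 had 10. The Y chromosome was part of the merged coverage and of the tested genes. No test was run on the scaffold peaks or on Y by itself.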

How the results depend on the processing

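The counting of every annotated gene, the intron windows of the same segment of the gene, the sums over bases and the restriction to autosomes were chosen after the data were seen. The read depth is unknown, so how far it sets the extent of coverage could not be examined. Under all alternatives run, the exon-to-intron ratio (1.23 to 4.35) and the ratio of gene end to gene start (2.98 to 4.48) stayed above 1 and past their threshold. The share of covered bases shared by the replicates was 53.8% as reported, 53.6% at a −log10 q of at least 2, 48.6% at 5, 53.5% with only the 88141 peaks of smallest p in each replicate and 66.2% with peaks joined over 1 kb. The share of replicate 1 peaks that met a replicate 2 peak was 83.3%, 82.5%, 77.1% and 74.3% under the same 4 settings and 74.8% when 50% of the peak had to be covered. For replicate 2 peaks these shares were 61.0%, 52.4%, 63.8%, 58.4% and 49.4%. Coding gene bodies held 94.7% of covered bases at a −log10 q of at least 2 and 95.6% at 5, and genes of any kind held 95.4%. With each replicate alone the share was 94.4% to 94.6%. Marked genes numbered 7755 to 8580 with each replicate alone and 3346 among genes that overlap no other, where fewer genes are tested. With 88141 peaks in each replicate, which equals the lists but also makes both stricter, 126 genes were marked in replicate 1 alone, and X coverage was 0.484%. By the share of genes marked, 10 lists passed that had not passed on the median: limb patterning at 11.1%, skeletal muscle at 3.23%, epidermis at 4.76%, endothelium at 7.14%, and the Hox, erythroid, neuron, liver, heart and olfactory receptor lists at 0%. Tendon and connective tissue no longer passed, at 58.3%, and the H3K36 methylation list no longer passed among the 5 members that overlap no other gene, at a median of 46.0%, fewer genes being tested. The neuron list had under 5 such members and gave no value there. For the other moves the cause was not tested. Of the remaining values of the comparisons, 243 kept their direction and their side of the threshold, moved by less than the replicate SD or, for counts, stayed within 1.5 times the reported count. Many of these are medians of gene lists that were 0 as reported and stayed at 0. A median of 0 cannot fall, so this number says little about stability. Within the bound for counts, marked genes numbered 5167 at a −log10 q of at least 5, 5944 at a limit of 20% and 8784 at a limit of 5%, against 7697 as reported. At a −log10 q of at least 5, where these lists still passed, medians were 15.9% for tendon and connective tissue, 32.7% for cell cycle, 27.6% for H3K36 methylation and 16.4% for Zfp genes. For the percent covered of the named genes, 628 values moved by less than that SD and 205 by more. No paired analysis was possible because the labels give 1 group only.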

Other observations

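The tests on the X chromosome were chosen after its low coverage was seen, the intron windows matched on the segment of the gene, alone or with GC content, after other results were seen, and the other tests before their results were examined.

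Some genes annotated as non-coding were also covered over most of their body. Among those of at least 5 kb clear of coding genes the most covered was Snhg17, a small nucleolar RNA host gene on chromosome 2, at 68.0% ± 6.88 (SD, n = 2). Gm20342 on chromosome 1 had 67.1% ± 7.64, Tmem134, annotated here as a processed transcript, 60.3% ± 5.04, and 5430416N02Rik 57.0% ± 6.17. Mirg, a microRNA-containing transcript of the imprinted region of chromosome 12, had 54.1% ± 8.97 (27.7% at a −log10 q of at least 5). All of these but Tmem134 overlapped another annotated gene.

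Coverage continued past annotated gene ends. In 530 marked genes with no other annotated gene within 10 kb, 49.4% ± 7.57 (SD, n = 2) of the last 2 kb of the gene was covered, 32.2% ± 6.70 of the 2 kb past the 3′ end, 7.42% ± 2.13 of the stretch from 2 to 5 kb and 1.86% ± 0.553 of that from 5 to 10 kb. Of the 2 kb before the 5′ end 0.0939% ± 0.0340 was covered. The hypothesis was that transcription runs past the annotated end, which predicted more than 3 times as much coverage there as before the start. The ratio was 393 in replicate 1 and 313 in replicate 2, which decides little: coverage before the start was near 0, so nearly any coverage past the end passes, and 3′ exons longer than annotated would give the same. Whether transcription runs past the end stays open.

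Among marked genes longer ones had a smaller share of the body covered, with a Spearman's rho across genes of -0.278 in replicate 1 and -0.225 in replicate 2. Marked genes are chosen by coverage itself, and over all tested genes rho was of the opposite sign, 0.117 and 0.118. The hypothesis that length itself goes with lower coverage was put to 109 genes of the housekeeping, splicing, cell cycle and H3K36 methylation lists. There rho was -0.0613 and -0.0236 (permutation p = 0.53 and 0.81), nearer 0 than the bound of -0.1 set beforehand. The correlation seen among marked genes was thus not found in these genes. A weaker one cannot be excluded with 109 genes, so whether length itself matters stays open. Genes are not independent replicates.

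Internal exons were richer in GC than random windows of their own introns, 51.0% against 44.4%. Matching on GC kept 77.4% of the log2 ratio in replicate 1 and 81.1% in replicate 2, which argues against GC content as the whole cause. Matching on the segment of the gene, 1 of 10 equal ones, kept 49.1% and 46.5%, between the bounds of 25% and 50% set beforehand. Position towards the 3′ end may thus account for a good part of the excess, but how much cannot be told apart from finer effects within a segment. Position inside a segment was not matched, so the remaining ratio of 1.40 does not decide whether position is the whole cause. With both matched 29.4% and 30.03% remained. This last comparison used 41760 exons against 53394 with random windows, and mean exon coverage was 48.6% against 51.8%. The fall can therefore not be laid to matching alone. Only GC content and segment were matched, and other technical differences between exons and introns were not examined. No biological explanation was tested.

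The low coverage of X may reflect which genes lie there or how strongly they were enriched. The first reading was tested on the lists of general cell functions: housekeeping, ribosomal, splicing, cell cycle and H3K36 methylation. Their 6 X-linked members had a median of 4.19% ± 1.39 (SD, n = 2) against 49.5% ± 7.54 for the 171 autosomal ones (permutation p = 1e-05, the smallest it can give). The permutation moved single genes, unmatched on length or list. Genes of the same chromosome are not independent, so this p does not test the chromosome. Rps4x, Rpl39, Rpl10 and Rpl36a among the 6 are ribosomal protein genes. The ratio of the medians was 0.117 and 0.0584 in the replicates, which argues against a mere lack of such genes, though on these 6 genes only. Enrichment close to the peak threshold stays open. At a −log10 q of at least 5 the X-to-autosome ratio was 0.357 and 0.414 of its value in the deposited lists, and the 99th percentile of fold on X, 4.27 and 4.77, was under that of every autosome, 5.18 and 5.92 at the lowest. The explanation was drawn from the same widening of the gap at stricter thresholds, so these values cannot support it. Both replicates pooled embryos of both sexes, and a lower number of X copies in males or the silent X of females stays open and was not tested.

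The high fold of Zfp genes was set against their long last exons, a median of 2.89 kb in 281 covered Zfp genes against 1.63 kb in other covered genes. The highest fold in the last exon had a median of 4.57 in replicate 1 and 5.49 in replicate 2, above the 3.84 and 4.44 that bound the central 95% of lists matched on last-exon length. Reads shared between neighbouring paralogs were tested with the 103 Zfp genes that have no other within 200 kb. Their medians were 4.42 and 5.13, above the matched bounds of 3.96 and 4.61. Neither last-exon length nor a Zfp gene within 200 kb thus accounts for the whole pattern. Reads shared with more distant paralogs, or with zinc-finger genes of other names, were not examined and stay open. The control signal at these genes, which enters the fold, was not analysed here, and a biological origin may be considered only as a hypothesis.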
